A study of Pseudomonas phage PAK_P4 and Pseudomonas aeruginosa with 12 samples.

How the data were processed

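RNA from *Pseudomonas aeruginosa* PAK infected with phage PAK_P4 was sequenced at 3.5 and 13 min for the phage and at 0 and 13 min for the host, with 3 samples per group as the sample titles state. Per the labels' protocols, infection was stopped by rapid cooling in diluted phenol, RNA was extracted with TRIzol, treated with DNase and depleted of ribosomal RNA, and libraries were made with a stranded kit. Per the submitters' processing notes, Bowtie 1.0.1 and DESeq2 were used, with no version of DESeq2, and the genome build is not given in the sources used here.

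The phage tables hold, per the file headers, 1 column per library and strand for 191 features. These values are headed as counts, but the deposited columns headed as normalized are their means within 0.67, and low values of replicate 2 at 3.5 min rise in steps of 3.64 on the sense strand (100% of 30 low values on a step within 0.5) and 4.54 on the opposite strand (99.4% of 171). The phage values were therefore read as a signal, counts divided by a size factor and rounded by the authors, and the sense and opposite strand of a feature as scaled apart. No step above 3 was found in the other libraries, so reads could not be recovered for all of them and no count model was fitted. The authors also deposited a fold (3.5 min over 13 min), a p-value rounded to 2 decimals and a mark per phage feature. On the sense strand 87 features carry the mark, and 73 of these passed here. Of all 191 features 161 passed, about the same share, so the overlap shows no match with the marks beyond that share. Host tables hold, per the file headers, the authors' mean normalized signal at 0 and late time, their log2 fold change, their p-value and adjusted p-value (the fold change is not the ratio of the means, and how it was derived is not given in the sources used here), and their marks, which in the gene sheet (930 features) also ask for a log2 fold change of 1.3 and in the sheet behind their graph (1416) do not. The antisense means in these tables were not used, because the column headed 0 min repeats the sense mean at 13 min and the other could not be mapped beside the sense mean, so the antisense results rest on the antisense log2 fold change, p-values and marks alone. The late column was taken as 13 min from the workbook title and the sample labels. The deposited sheet behind the authors' graph also gives log10 of the mean signal and the authors' groups of features. No per-sample column was left unmapped.

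The design fixed before the data were examined assumed counts: the count test planned for both organisms was replaced, for the phage, by the planned fallback for normalized values and, for the host, by the authors' own adjusted p, because only means per time are given there. The tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined, apart from those said to be chosen later. For the phage, the sense strand was the one that the authors tested, and for 5 genes, tested on neither or both, the one with more signal. Values were scaled to each library's share of the sense total, because most genes of 1 phage can change their share at once, and log2(value + 1) of values rescaled to the mean total was fitted with limma 3.58.1 in R 4.3.3, with time as the only term, a two-sided moderated test and Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(value + 1) scale, which understates changes of low features. They are differences of mean log2 values, not ratios of the mean shares printed beside them. Where the libraries of a time differ, they can exceed those ratios. Shares were compared with exact two-sided permutation tests. Plus-strand and minus-strand genes were tested with limma's camera (preset correlation 0.01), adjusted over both. The blocks of neighbouring genes on 1 strand were defined from the tables after they were seen and adjusted over the blocks and the antisense RNAs. Phage genes carry no product names in the tables, so functional classes and genes planned by product were not analysed here. Locus names of phage genes are given without their prefix, and coordinates are not given in the sources used here.

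For the host, 32 lists of symbols or product words were matched to 6510 features, 1211 of which carry a symbol. A list's median log2 fold change was placed among 10000 random lists of the same size matched on the mean signal of both times in 20 bins, for lists with at least 5 members. This percentile describes these libraries and is no p-value. Counts of members use the authors' adjusted p over all features and, beside it, Benjamini-Hochberg over the list alone. Percentiles and readjusted p were computed with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and figures drawn with matplotlib 3.10.9. The limma p-values set a difference against the spread between the libraries of a time. Camera with its preset correlation sets a group of features against the other features. The authors' host p-values were taken as deposited.

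Host features were named by a rule: the 8 largest rises and 8 largest falls that passed, with a mean of at least 50, annotated and not ribosomal or transfer RNA; the 3 largest each way whatever the annotation; for each list up to 3 members with the smallest p in the more frequent direction and 1 in the other; and rpoD, rpoS, recA, the RNase E gene and oprF. Phage features were named as the 6 largest rises and falls, the 5 most abundant at each time and 3 per group, and antisense and non-coding features as the 4 with the smallest p each way. The part of the host rule that asks for libraries that do not overlap could not be applied to means. PAK_4107, PAK_n019, PAK_n023 and PAK_n001 and the members of the authors' groups were named after their values were seen.

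The calculations were tried on simulated data. In 191 simulated phage features with an SD of 0.65 between libraries and 40 changed, limma recovered 43.8% of changes at a log2 fold change of 1.5 and 99.7% at 3, and called 3.1% of unchanged features. Camera called 0% of unchanged groups and 100% of groups shifted by 1. The simulated noise was independent between features and the groups were random, whereas the estimated correlation within gp001 to gp034 was 0.78. The camera rates therefore do not carry over to the blocks. The simulated changes went both ways and no block took over the signal, so the rate among unchanged features does not carry over to falls by share. Of 200 random lists of 20 among 6474 host features, 5.0% fell outside the central range, and 99.0% of lists shifted by 1 lay above it. Alternatives were trimmed-mean and median-ratio factors, values as deposited, pseudocounts of 0.5 and 5, a mean of at least 50, a log2 fold change of at least 1, leaving out each library, a term for the replicate number, an estimated correlation and fry for the phage, and other filters, thresholds and list references for the host. Read depth is unknown for the host and for all phage libraries but replicate 2 of 3.5 min, so no counting interval is given.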

Results

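The study followed an infection of *Pseudomonas aeruginosa* strain PAK by the lytic bacteriophage PAK_P4. Bacteria were grown in LB with 10 mM MgCl2 at 37 °C to an optical density of about 0.3 and infected synchronously. RNA was depleted of ribosomal RNA and sequenced with a strand-specific kit. The 12 samples comprised phage transcripts at 3.5 and 13 min (3 libraries each) and host transcripts at 0 and 13 min (3 libraries each), which the series describes as biological replicates. The phage tables gave values per library, and summed sense values were 4352001, 5203998 and 5163555 at 3.5 min and 10985700, 12227618 and 11535633 at 13 min. These totals are sums of values already normalized by the authors, so the read depth behind them is unknown for all but replicate 2 of 3.5 min. Its total divided by the step of its low values is 1430849. The host tables gave the authors' mean per time point only, so host values have no error between libraries here.

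The first phage question was which genes changed their share of phage transcripts between 3.5 and 13 min. Genes gp001 to gp034, a block on the plus strand, took 4.35% ± 2.88 (SD, n = 3) of the phage sense signal at 3.5 min and 52.1% ± 1.14 (SD, n = 3) at 13 min. The long plus-strand block gp041 to gp125 went the other way, from 56.7% ± 6.36 to 25.6% ± 0.875 (SD, n = 3 each), and the minus-strand block gp126 to gp170 went from 29.0% ± 3.53 to 14.7% ± 0.388 (SD, n = 3 each). The 17 antisense RNAs went from 1.79% ± 0.127 to 0.338% ± 0.0924 (SD, n = 3 each). The 10 most abundant features at 13 min held 43.9% ± 1.37 of the signal at that time and 6.33% ± 4.56 at 3.5 min (SD, n = 3 each), a set picked on these libraries. Without replicate 3 of 3.5 min the second share was 3.71%. Each of these 5 shares differed with an exact two-sided permutation p = 0.1, the smallest that 3 libraries against 3 allow. The shares are parts of 1 total, so the rise of gp001 to gp034 lowers the others, and these are not separate differences. With the values as deposited, the median log2 fold change was 0.17 for gp126 to gp170, -0.48 for gp041 to gp125 and -1.17 for the antisense RNAs.

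**Figure D1:**
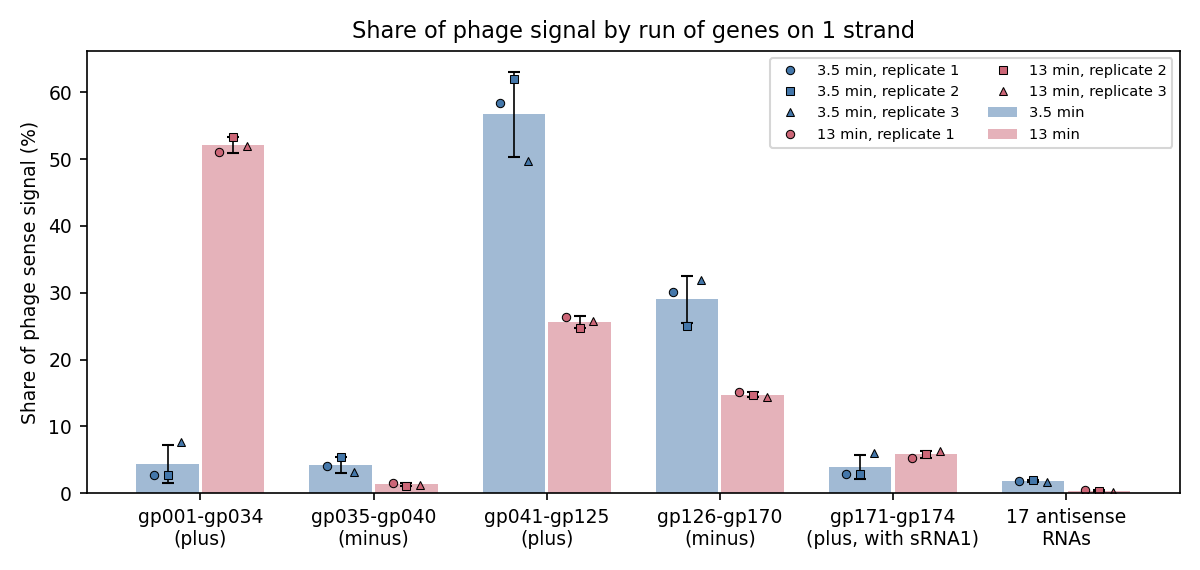
Share of the phage sense signal (percent, vertical axis) held by each block of neighbouring genes on 1 strand and by the antisense RNAs, at 3.5 min (blue) and 13 min (red). Bars are means of 3 libraries, error bars are SDs and symbols are single libraries; the block gp001 to gp034 stood at 4.35% and 52.1%.

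The largest rises were in that first block. The share of gp006 went from 0.00564% ± 0.00742 to 6.20% ± 0.161 (SD, n = 3 each), a log2 fold change of 11.04 (SE 0.93, limma adjusted p = 2.2e-04). Genes gp005 (log2 fold change 10.62), gp032 (9.98), gp034 (9.79), gp004 (9.40) and gp033 (9.40) followed, and gp010 (8.75), gp009 (8.51) and gp008 (5.35) had the smallest p in the block; gp032 was listed at 0 in replicate 2 of 3.5 min. The place of gp032 depends on the pseudocount, with a log2 fold change of 10.37 at 0.5 and 8.89 at 5, where it lies below gp034, gp004 and gp033. Replicate 3 at 3.5 min held 7.68% of its signal in this block against 2.67% and 2.71% in the other libraries of that time. Without it the log2 fold change was 12.17 for gp006, 11.83 for gp005, 11.67 for gp032, 11.13 for gp034, 11.08 for gp004 and 10.64 for gp033. Leaving out replicate 1 or 2 of 3.5 min, which gives replicate 3 more weight, lowered all of them. The values were then 10.31 or 10.63 for gp006, 9.69 or 8.56 for gp032 and 8.52 or 8.61 for gp004. Replicate 3 thus lowers these changes. Abundant transcripts at 13 min also included gp011 and gp002. The share of gp011 rose from 0.392% ± 0.0875 to 6.06% ± 0.216 (log2 fold change 3.97). That of gp002 rose from 0.156% ± 0.240 to 5.75% ± 0.319 (log2 fold change 6.84, and 8.40 without replicate 3 of 3.5 min). Without that library the share of gp002 at 3.5 min was 0.0171%. The value of 6.84 is a difference of mean logs and exceeds what the ratio of its mean shares gives.

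Outside the block, gp059 had the highest mean share at both times, at 3.23% ± 1.43 and then 6.97% ± 0.533 (log2 fold change 1.20, SE 0.34, limma adjusted p = 0.015). At 3.5 min that rank rests on replicate 3, without which gp098 (2.85%) and gp120 (2.65%) stood above gp059 (2.45%). The call of gp059 was lost without replicate 1 of 3.5 min (adjusted p = 0.0507) and without replicate 3 of 13 min (0.0514). The small RNA PAK_P4sRNA1 stood at 1.34% ± 1.66 and 3.86% ± 0.679 (log2 fold change 2.30, SE 0.85, limma adjusted p = 0.040). Without replicate 3 of 3.5 min its share at that time was 0.380% and its log2 fold change 3.33. Its call depended on which libraries were used: the adjusted p was 4.3e-07 without replicate 3 of 3.5 min and between 0.0734 and 0.137 without any other single library, and its share differed with an exact two-sided permutation p = 0.2. It lies in the block gp171 to gp174, which held 3.88% ± 1.82 and 5.82% ± 0.489 of the signal (exact two-sided permutation p = 0.3). There gp171 had a log2 fold change of 0.79 (limma adjusted p = 0.023), between 0.0511 and 0.087 without any single library other than replicate 3 of 3.5 min, and gp173 had -1.33 (limma adjusted p = 0.005). The fall of gp173 disappeared with the values as deposited (log2 fold change -0.09).

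The largest falls were in gp112 (log2 fold change -3.26, SE 0.44, limma adjusted p = 7.0e-04), gp122 (-3.22) and gp120 (-3.17), which went from 2.26% ± 0.691 to 0.244% ± 0.0481 of the signal, and in the antisense RNAs PAK_P4as06 (-3.10), PAK_P4as12 (-2.92) and PAK_P4as15 (-2.87). The other antisense RNAs with the smallest p were PAK_P4as04 (-2.29), PAK_P4as05 (-2.62) and PAK_P4as09 (-2.60). Of the abundant genes at 3.5 min, gp098 went from 2.57% to 0.493%, gp076 from 2.27% to 0.775% and gp110 from 2.12% to 0.361%. In the block gp041 to gp125, gp119 (-2.79) and gp106 (-2.19) were also among the smallest p. In the minus-strand block gp126 to gp170, gp135 fell by 2.11, gp128 by 1.95 and gp132 by 1.56 on the log2 scale. The short minus-strand block gp035 to gp040 held 4.22% ± 1.15 and then 1.33% ± 0.240, and its members gp036 (-1.85), gp040 (-1.70) and gp037 (-1.41) all fell as shares. With the values as deposited, without scaling to shares, gp076, gp132, gp036, gp037 and gp040 no longer passed.

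**Figure D2:**
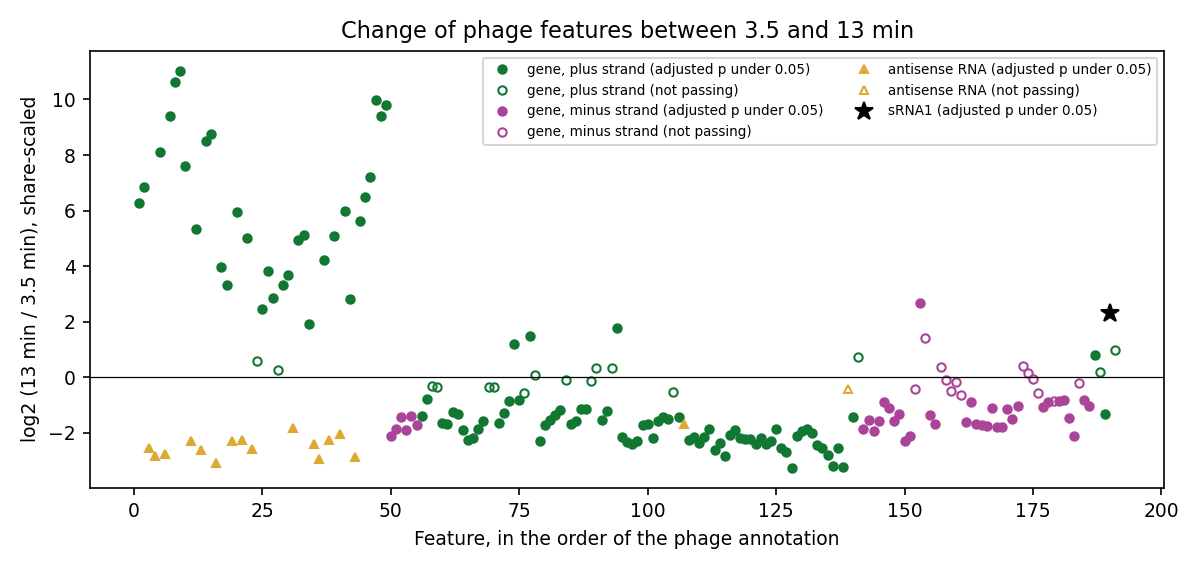
The log2 fold change of each phage feature between 3.5 and 13 min (vertical axis, scaled to the sense total) against its order in the phage annotation (horizontal axis). Filled symbols passed an adjusted p of 0.05 in limma; gp006 reached 11.04, and the median over all 191 features of -1.40 became -0.16 with the values as deposited, so small falls depend on the scaling.

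Of 191 phage features, 161 passed an adjusted p of 0.05 in limma. By share, 38 rose (37 genes and the small RNA) and 123 fell (107 genes and 16 antisense RNAs). Of the 34 genes gp001 to gp034, 32 rose and 0 fell. The block gp041 to gp125 had 3 rises and 69 falls among 84 genes, the block gp126 to gp170 had 1 rise and 31 falls among 45, all 6 genes gp035 to gp040 fell, and gp171 to gp174 with the small RNA had 2 rises and 1 fall among 5. Only the first block and the antisense RNAs had most of their members passing in 1 direction under every scaling. The medians of gp035 to gp040 and gp041 to gp125 stayed below 0 under every scaling and that of gp171 to gp174 above 0, with fewer or other calls. The split of calls into higher and lower was 38 and 123 by share, 58 and 43 with the values as deposited, 56 and 47 with trimmed-mean factors, and 61 and 41 with median-ratio factors. With the values as deposited all 34 genes of the first block rose, the block gp041 to gp125 had 13 rises and 27 falls, and the block gp126 to gp170 had 7 rises and 3 falls, with its median turning from -1.07 to 0.17. The 17 antisense RNAs had 0 rises under each scaling and 16 falls by share, and their median was -2.41 by share and -1.17 as deposited.

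Genes were also compared by strand, a grouping fixed in advance. Of the 123 features on the plus strand 37 rose and 70 fell, and of the 51 on the minus strand 1 rose and 37 fell by share. The plus strand held 64.9% ± 2.30 of the signal at 3.5 min and 83.6% ± 0.657 at 13 min, and the minus strand 33.3% ± 2.41 and 16.1% ± 0.595 (SD, n = 3 each, exact two-sided permutation p = 0.1 for each). These too are parts of 1 total and not separate differences. Camera placed plus-strand genes above the others (adjusted p = 6.4e-04, and adjusted p = 0.0324 with an estimated correlation) and minus-strand genes below (adjusted p = 0.0252, and adjusted p = 0.194 with an estimated correlation). With median-ratio factors neither group passed, so these calls depend on the scaling. Of the 10 splits of the libraries 5, the real one included, called both groups. Every other split mixes the 2 times unevenly and keeps part of the time difference, so these splits cannot judge the p-values. The signs differ for the plus strand: its median log2 fold change was -1.30 and the rotation test fry gave a fall (adjusted p = 5.4e-04), while the first block, on the same strand, had a median of 5.49. The medians of the plus and minus strand were -0.06 and 0.10 with the values as deposited, where the minus-strand group did not pass (adjusted p = 0.835), and it did not pass without replicate 3 of 3.5 min (adjusted p = 0.0602). For the blocks, which were drawn from the strand order after the values were seen, camera with its preset correlation gave adjusted p = 3.3e-44 for gp001 to gp034, 7.0e-06 for gp041 to gp125 and 0.00879 for the antisense RNAs. With an estimated correlation the adjusted p was 0.0659 for the first block and between 0.323 and 0.543 for the others.

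The host comparison asked which bacterial transcripts changed between 0 and 13 min of infection. In the authors' deposited table the largest rises were in neighbouring genes PAK_4098 to PAK_4109, whose annotated products include a thiazolinyl imide reductase and an isochorismate synthase, enzymes of siderophore synthesis. PAK_4100, an amino acid adenylation domain protein, went from a mean of 18.1 to 4140 in the authors' deposited table (log2 fold change 7.03, adjusted p = 4.6e-32). The deposited fold changes are not the ratios of the deposited means: for PAK_4100 the authors' deposited table gives a 130-fold change by log2 and 228-fold by the means. Genes of a P2-like prophage also rose, with PAK_6301, a phage minor tail protein, at a log2 fold change of 5.13 (adjusted p = 9.1e-12) in the authors' deposited table. Of 75 features with transfer RNA words in their product 41 fell and 2 rose, with the tRNA-Tyr PAK_4159 at -3.88 (adjusted p = 9.1e-19) in the authors' deposited table. Of 39 potential small RNAs 18 fell and 2 rose, the largest fall being PAK_n037 at -4.12 (adjusted p = 5.7e-14) in the authors' deposited table. Among 6510 features in that table, 473 were higher and 943 lower at an adjusted p under 0.05.

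**Figure D3:**
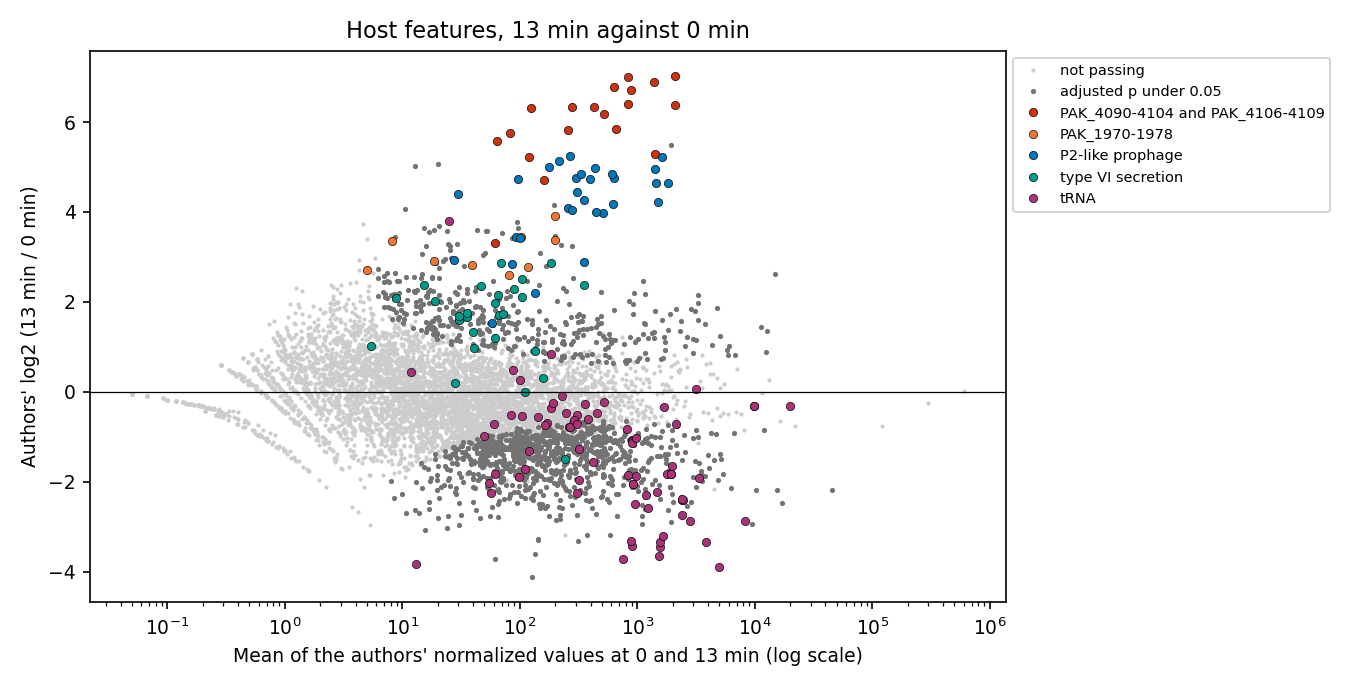
The authors' log2 fold change of each host feature (13 min against 0 min, vertical axis) against the mean of the authors' normalized values at both times (horizontal axis, log scale), with named groups in colour. In the authors' deposited table PAK_4100 stands at 7.03 and the tRNA-Tyr PAK_4159 at -3.88.

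The host samples hold no uninfected culture at 13 min, so time and infection cannot be separated. Host values were normalized by the authors, and the amount of host RNA per cell is not given in the sources used here. Host rises and falls are therefore relative to other host RNA, and a change of host RNA as a whole could not be seen. The median log2 fold change of 6474 features was -0.18 in the authors' deposited table, and scaling to equal summed means would add 0.32 to every value, which moves that median to 0.14. That shift is smaller than the smallest change among the 1416 calls (0.64), so it can turn none of them and says nothing on how firm they are.

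The authors' deposited table gave further rises for PAK_4102, a phosphopantetheine attachment site protein (7.01), PAK_4099, a methyltransferase domain protein (6.90), PAK_4101, a condensation domain protein (6.77), and PAK_4109, the isochorismate synthase (6.72). In the authors' deposited table PAK_4098, the thiazolinyl imide reductase, stood at 6.40, PAK_4103 at 6.37, PAK_4106 at 6.34 and PAK_4107 at 6.31. The authors grouped these neighbours themselves, and in their deposited table all 15 members of PAK_4090 to PAK_4104 rose (log2 fold changes 3.32 to 7.03; 15 adjusted over the list alone), as did all 4 of PAK_4106 to PAK_4109 (4 adjusted over the list alone). A separate group of the authors, named only by its range PAK_1970 to PAK_1978, had 8 of 9 members higher in their deposited table (9 adjusted over the list alone). It held the siderophore receptor PAK_1970 at 3.90 and the peptide synthases PAK_1976 at 3.44 and PAK_1977 at 3.39. The authors' P2-like prophage group had 28 of 30 members higher in their deposited table (30 adjusted over the list alone), including PAK_6303 (5.25) and PAK_6290 (5.22). Groups chosen by the authors on these samples are not independent evidence of a direction. The list of iron uptake symbols fixed in advance matched 1 feature, feoB, a ferrous iron transporter, at 1.52 (adjusted p = 0.00406) in the authors' deposited table.

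Of the lists fixed in advance, prophage and phage-related products had the highest median. Of 20 measured members 13 rose and 1 fell in the authors' deposited table (13 and 2 adjusted over the list alone; median 4.04, percentile 100 of 10000 random lists matched on mean level). Next to PAK_6301, the tail tape measure protein PAK_6300 stood at 4.96 and the tail sheath protein PAK_6287 at 4.64 in the authors' deposited table, while the integrase PAK_2537 fell by 0.98. Type VI secretion, a contractile apparatus that delivers effectors into neighbouring cells, had 14 of 21 members higher and 1 lower in the authors' deposited table (15 and 1 adjusted over the list alone; median 1.76, percentile 100). Its ATPase gene clpV1 stood at 2.86, tssF1 at 2.86 and tssM1 at 2.37 in the authors' deposited table, and fha1 at -1.49. The authors' own type VI group, not independent evidence, had 17 of 27 members higher and 1 lower in their deposited table (22 and 1 adjusted over the list alone). In the TCA cycle 8 of 14 members rose and 1 fell in the authors' deposited table (8 and 1 adjusted over the list alone; median 1.10, percentile 100), with sucB at 2.47, sucA at 1.97, acnB at 1.58 and the isocitrate dehydrogenase icd at -1.48. Phenazine synthesis had 2 of 8 higher and 0 lower in the authors' deposited table (3 and 0 adjusted over the list alone, median 1.304, percentile 99.9), from low means: phzE2 went from 5.53 to 22.8 (1.89) and phzS from 7.75 to 21.0 (1.37). Antisense signal opposite both genes rose by more in the authors' deposited table, by 2.03 for phzE2 (adjusted p = 0.00148) and 4.74 for phzS (adjusted p = 1.15e-14). What the sense rises reflect was not tested. Exopolysaccharide genes had 2 of 32 higher and 1 lower in the authors' deposited table (2 and 1 adjusted over the list alone, median 0.60, percentile 99.9), with pelF at 2.01, pslF at 1.66 and pslA at -1.65. Both rises were from low means: pelF went from 4.28 to 22.0 and pslF from 9.05 to 31.1.

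Transfer RNAs carry amino acids to the ribosome. Of 75 features taken for them by product words, 41 were lower and 2 higher in the authors' deposited table (46 and 2 adjusted over the list alone, median -1.30, percentile 0). The words match any product that begins with tRNA. Whether genes of enzymes acting on transfer RNA are among these features was not checked. The tRNA-Arg PAK_1256 stood at -3.71 and the tRNA-Glu PAK_2540 at -3.64 in the authors' deposited table, against 3.81 for the tRNA-Arg PAK_4491. Transposases and integrases had 3 of 9 lower and 0 higher in the authors' deposited table (4 and 1 adjusted over the list alone; median -0.98, percentile 1.03), the transposases PAK_2348 at -1.60 and PAK_347 at -1.22 and the integrase PAK_2537. In the protein secretion machinery 7 of 15 fell and 1 rose in the authors' deposited table (8 and 2 adjusted over the list alone; median -0.83, percentile 14.3). The translocase genes secE and yajC stood at -2.44 and -1.71 and ffh at -1.05 in the authors' deposited table, while secY stood at 0.89. Type IV pili, the surface fibres of twitching motility, had 10 of 29 members lower and 2 higher in the authors' deposited table (11 and 2 adjusted over the list alone; median -0.50, percentile 48.1), with pilZ at -2.07, pilI at -1.57, pilK at -1.56 and chpA at 0.86.

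Ribosomal protein genes moved both ways, 13 of 49 higher and 14 lower in the authors' deposited table (15 and 15 adjusted over the list alone; median 0.13, percentile 99.6). There rpmF stood at -2.54, rpsP at -1.91 and rplM at -1.75, against rplV at 2.17 in the authors' deposited table. RNA polymerase and sigma factors had 3 of 16 higher and 5 lower in the authors' deposited table (3 and 6 adjusted over the list alone; median -0.46, percentile 54.7). The polymerase subunit gene rpoC rose by 2.62 in the authors' deposited table (adjusted p = 6.7e-17), nusG stood at -1.97, greB at -1.62 and the housekeeping sigma factor gene rpoD at -1.40 (adjusted p = 5.2e-05). RNA degradation and processing had 2 of 10 higher and 4 lower in the authors' deposited table (2 and 4 adjusted over the list alone; median -0.51, percentile 48.5): the regulator csrA stood at -2.93, the RNA chaperone hfq at -2.63, rnpA at -1.95 and pnp at 1.013. Hfq was also a group of the authors, so its direction is not independent evidence. SOS and DNA repair had 3 of 18 higher and 2 lower in the authors' deposited table (3 and 2 adjusted over the list alone; median -0.37, percentile 68.8), with recD at 1.33, recB at 1.29, recC at 0.70 and recG at -1.06. In DNA replication 6 of 21 fell and 0 rose in the authors' deposited table (6 and 1 adjusted over the list alone; median -0.09, percentile 93.8), with ssb at -1.82, ihfA at -1.74 and dnaA at -1.19.

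Type III secretion had 6 of 35 members lower and 2 higher in the authors' deposited table (7 and 2 adjusted over the list alone; median -0.07, percentile 97.6), with the activator exsA at -1.90, pcrG at -1.61, pscO at -1.45 and popD at 1.46. Amino acid synthesis had 3 of 28 lower and 0 higher in the authors' deposited table (3 and 0 adjusted over the list alone; median -0.07, percentile 98.0), with metX at -1.74, lysA at -0.80 and dapA at -0.77. For both lists the percentile lay high although the members that passed mostly fell. Translation factors had 3 of 14 higher and 3 lower in the authors' deposited table (3 and 3 adjusted over the list alone; median -0.12, percentile 85.9), with fusA at 1.35, infB at 0.81, rbfA at 0.69 and efp at -1.87. Heat shock and protease genes had 2 of 10 higher and 2 lower in the authors' deposited table (2 and 2 adjusted over the list alone; median -0.21, percentile 78.2), with dnaJ at 1.13, dnaK at 0.69 and hslV at -1.21. Nucleotide synthesis had 5 of 31 lower and 2 higher in the authors' deposited table (5 and 2 adjusted over the list alone; median -0.23, percentile 87.6), with pyrD at -1.47, prs at -1.46, pyrE at -0.97 and carB at 1.37. Cell division and peptidoglycan had 5 of 18 lower and 3 higher in the authors' deposited table (5 and 3 adjusted over the list alone; median -0.29, percentile 77.1), with minE at -1.92, zipA at -1.44, ftsL at -1.28 and ftsZ at 1.20.

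ATP synthase had 3 of 9 lower and 1 higher in the authors' deposited table (3 and 1 adjusted over the list alone; median 0.04, percentile 84.1), with PAK_5601 at -2.41, atpB at -1.89, atpE at -1.23 and atpA at 1.03. Flagellum and chemotaxis had 4 of 36 lower and 1 higher in the authors' deposited table (4 and 1 adjusted over the list alone; median -0.33, percentile 81.7), with flgD at -1.54, flhB at -1.39, cheY at -1.34 and the anti-sigma factor gene flgM at 1.11. Outer membrane assembly had 4 of 11 lower and 0 higher in the authors' deposited table (5 and 0 adjusted over the list alone; median -0.40, percentile 60.6), including lolB at -1.11, lpxC at -1.02 and lpxA at -0.87. Arginine and polyamine genes had 3 of 17 lower and 0 higher in the authors' deposited table (4 and 0 adjusted over the list alone; median -0.44, percentile 34.9), with speE at -1.41, speD at -1.11 and argA at -0.75. Quorum sensing had 1 of 16 higher and 1 lower in the authors' deposited table (1 and 1 adjusted over the list alone; median 0.16, percentile 64.0), pqsA at 2.17 and lasR at -1.13. Denitrification had 1 of 8 higher and 0 lower in the authors' deposited table (1 and 0 adjusted over the list alone, median -0.03, percentile 63.9), narJ at 2.53. Both pqsA and narJ rose from low means, pqsA from 1.96 to 12.4 and narJ from 1.19 to 11.1. Restriction, CRISPR and toxin-antitoxin genes had 0 of 8 passing in the authors' deposited table (0 adjusted over the list alone; median 0.06, percentile 89.9). The small lists had no percentile: of 4 oxidative stress genes 2 fell in the authors' deposited table, trxA at -2.45 and ahpC at -1.14 (2 adjusted over the list alone), 1 of 4 NADH dehydrogenase genes fell, nuoD at -1.43 (2 lower and 1 higher adjusted over the list alone), and 0 of 2 pyocin genes passed (0 adjusted over the list alone). The list of RND efflux symbols matched 0 features.

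**Figure D4:**
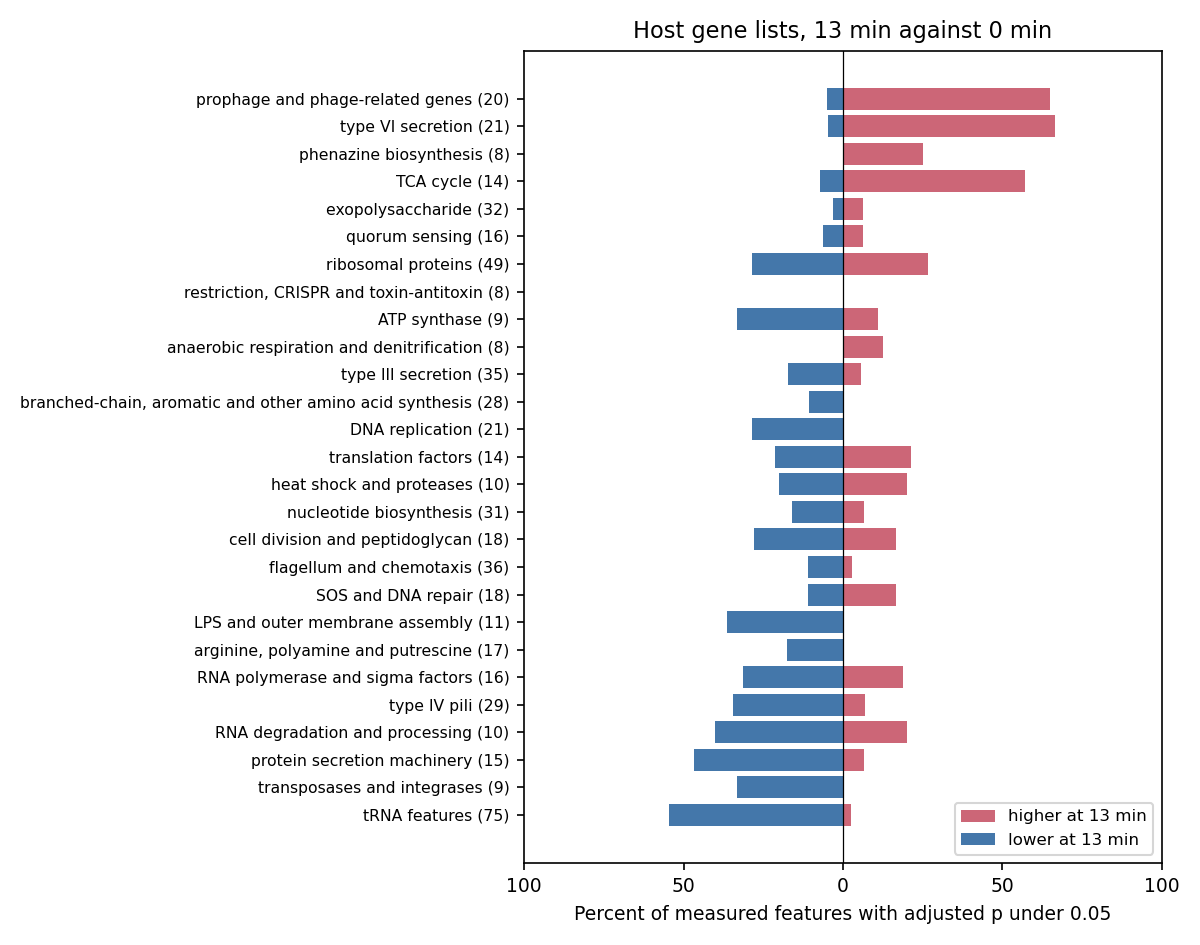
Percent of measured features in each host list that were higher (red, right) or lower (blue, left) at 13 min at an adjusted p under 0.05 in the authors' deposited table, sorted by the list's median; the number measured stands in brackets. Type VI secretion had 14 of 21 higher and features with transfer RNA words 41 of 75 lower. Scaling to equal summed means would add 0.32, too little to turn either median.

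Of 27 lists with at least 5 members, 10 had a median outside the central 95% of matched random lists, 8 above and 2 below. Moving each list along the feature order in place of matching gave 8, of which 7 were shared, and lost ribosomal proteins (percentile 89.4), type III secretion (64.9) and amino acid synthesis (68.3), and gained protein secretion (1.63). With the scaling to equal summed means the medians of 8 lists, all between -0.29 and -0.03, turned from below to above 0.

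Other single genes chosen in advance were rpoS, at -0.66 (adjusted p = 0.215), and recA, at -0.55 (adjusted p = 0.261), in the authors' deposited table. No symbol matched the porin gene oprF or the RNase E gene, and features with those words in their product stood in the authors' deposited table at -0.85 (PAK_1232, adjusted p = 0.0401), 0.59 (PAK_2720, adjusted p = 0.129) and -0.53 (PAK_4376, adjusted p = 0.279). Among annotated proteins with the largest falls, the authors' deposited table gave the leucyl tRNA synthetase PAK_3297 (-3.17), the export protein SecG PAK_4693 (-2.94) and the cold-shock protein PAK_550 (-2.90), and a hypothetical protein, PAK_542, stood at -3.59.

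Non-coding RNAs were compared as a separate sheet. Of 121 features 60 fell and 4 rose in the authors' deposited table with p adjusted over non-coding features (52 and 4 over all features), and the median there was -0.94. The authors drew these features as a group of their own, so the direction is not independent evidence. Apart from PAK_n037, the potential small RNAs PAK_n125 (-3.71), PAK_n046 (-3.30), PAK_n045 (-3.26) and PAK_n026 (-2.12) fell in the authors' deposited table. The 4 that rose in the authors' deposited table were PAK_n013, annotated as a partial ribosomal RNA (3.29), the potential small RNAs PAK_n057 (2.57) and PAK_n051 (2.30), and PAK_n018, a Pseudomon-1 RNA motif (1.74). The most abundant, RNase P RNA (PAK_n019), stood at 0.03 (adjusted p = 0.959), 6S RNA (PAK_n023) at -0.24 (adjusted p = 0.731) and CrcZ (PAK_n001) at -0.76 (adjusted p = 0.166) in the authors' deposited table, and together they held 38.6% of the summed means at 0 min and 43.5% at 13 min.

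Antisense signal was tested by the authors for each host gene. Of 3335 features with an adjusted p, 472 passed in the authors' deposited table, 357 higher and 115 lower at 13 min. The deposited p and adjusted p of sense and antisense features follow a joint ranking, so the authors appear to have adjusted both together. The rises with the smallest p lay opposite PAK_5176, a molybdopterin oxidoreductase (5.36), PAK_589, a sir2 family protein (3.76), PAK_588, a Fis family regulator (4.97), and PAK_3143, a transporter (4.32), in the authors' deposited table. The falls with the smallest p lay opposite PAK_4155 (-2.56), PAK_1255 (-3.34), PAK_3158 (-2.98) and PAK_4224 (-2.43) in the authors' deposited table. The antisense means were not used, since the column headed 0 min repeats the sense mean at 13 min, so the levels behind these fold changes were not checked. The sense strand also passed for 119 of the 472, in the same direction for 82 and the opposite for 37. The authors' own marks, stricter than the adjusted p alone, kept 171 in their deposited table, 100 higher and 71 lower.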

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

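The tests on replicate 3 of 3.5 min given here were chosen after the result was seen, as was the look at the opposite strand of the phage.

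Opposite-strand signal, outside the main measurement, stood at 3 or more in all 6 libraries for 172 of the 174 phage features other than annotated antisense RNAs, with no control sample to set it against. Opposite to gp001 to gp034 lay 84.4% ± 11.6 of this signal at 3.5 min and 65.7% ± 14.8 at 13 min (SD, n = 3 each), a difference about as large as the spread between libraries. Its totals were 155933, 149383 and 109781 at 3.5 min and 75301, 78030 and 59787 at 13 min, on a scale apart from that of the sense strand. Of the 17 annotated antisense RNAs most, such as PAK_P4as04 and PAK_P4as12, are listed between these genes, and whether they account for the signal was not tested.

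Replicate 3 of 3.5 min lay toward the 13 min libraries: its mean correlation with them across features was 0.400, against 0.0732 and 0.0380 for replicates 1 and 2, and features are not independent replicates. RNA of a 13 min sample mixed into it would add about the same percent of the 13 min value to each gene of gp001 to gp034. The highest excess was 18.5 times the median one (17.4 to 19.5 with either other replicate as the base). That was gp015, only 2.41 times replicates 1 and 2, so ordinary spread could give it and this measure cannot decide. For gp002 and gp006, both among the 5 most abundant at 13 min, the excess was 7.24% and 0.207%. An even admixture would not give both, but this rests on 1 library. A wrong scaling factor would move all features alike, but the median log2 ratio to replicates 1 and 2 differed by 2.61 between gp001 to gp034 and gp041 to gp125. An infection further along in that culture stays open as untested: the ratio fell with gene order over the first 10 genes (rank correlation -0.92), a stretch picked after it was seen, but not over all 34 genes of the block (-0.08). Replicate 3 held 7.68% of its signal in gp001 to gp034, against 52.1% ± 1.14 (SD, n = 3) at 13 min. Its mean correlation with its own group was 0.880. These values argue against an exchange of labels with a 13 min phage library. Any other mislabelled sample or a mistimed one was not tested.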

How the results depend on the processing

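Values as deposited, the authors' threshold and marks, the mean of at least 50 for the host, the other list references, the adjustment of non-coding features over all features and the tests of the blocks were chosen after the data were seen.

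Of the phage features, 161 passed by share (38 higher, 123 lower). Trimmed-mean factors gave 103 (56 and 47; 85 shared, all in the same direction), median-ratio factors 102 (61 and 41; 81 shared, 79 in the same direction) and values as deposited 101 (58 and 43; 81 shared, all in the same direction). These scalings put the median log2 fold change at -0.20, -0.06 and -0.16 in place of -1.40. The scaling itself thus, by construction, moves the split: falls dropped out and other features came in as rises. Leaving out each library gave 149 to 172 calls, 32 to 48 higher and 114 to 124 lower, and without replicate 3 of 3.5 min all 161 calls were kept. Pseudocounts of 0.5 and 5 gave 161 and 162, a mean of at least 50 gave 161 and a log2 fold change of at least 1 gave 151.

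The strand groups passing numbered 2 by share, 1 with trimmed-mean factors, 0 with median-ratio factors, 1 as deposited, 1 with an estimated correlation, 2 with fry and 1 to 2 when each library was left out (1 without replicate 3 of 3.5 min). The blocks passing numbered 3, but 0 with an estimated correlation, 5 with fry and 3 to 4 when each library was left out; apart from the estimated correlation and the scaling, the cause was not tested. Of 35 named phage features, gp173 reversed with median-ratio factors (0.0047, adjusted p = 0.985); 5 others were weaker there, 6 with trimmed-mean factors, 6 as deposited and 2 to 3 when a library was left out, while all 35 kept their calls with either pseudocount and without replicate 3 of 3.5 min.

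A replicate block gave 158 phage calls (39 higher, 119 lower), 2 strand groups and 3 blocks. Same-numbered libraries deviated with correlations of 0.23, -0.28 and 0.08 and did not each match their own number best. The numbers thus show no pairing, but so few libraries cannot exclude it.

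Other splits of the 6 phage libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split gave 161 features and the highest other 0 (1 split with as many), 2 strand groups against 2 (5 splits with as many) and 3 blocks against 5 (9 splits with as many). Every other split mixes the times unevenly and keeps part of the time difference, so these counts decide nothing on limma or camera. The preset camera tests still say little, because with an estimated correlation 0 blocks passed and the strand groups passing changed with the scaling.

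Of 1416 host features passing (473 higher, 943 lower), the authors' threshold of 1.3 left 930 (352 and 578), by its construction. A mean of at least 50 left 1229 (305 and 924), since it removes low features, where rises are frequent. Benjamini-Hochberg over all sense features with a p, unfiltered, gave 1432, a log2 fold change of at least 1 gave 1238 and leaving out structural RNAs 1369. Apart from the fold change limits, these alternatives were readjusted without the antisense tests. Lists outside the central range numbered 10 matched, 8 by moving along the order, 8 unmatched and 8 without structural RNAs. The authors' marks left 171 of 472 antisense features. Benjamini-Hochberg over all antisense features with a p, without the sense tests, gave 342, so that fall cannot be put down to the filter. Non-coding features went from 64 to 56 over all features and 49 with the threshold. The scaling to summed means, smaller than any change among host calls, can turn no call; of 132 named host features it turned PAK_n023, which did not pass, from -0.24 to 0.08.

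Replicate-based alternatives (other factors, DESeq2, camera, fry, pseudocounts, leaving out libraries, a block) were not run for the host, since only means were used, and DESeq2 was not run for the phage, which has no counts here. What depth limits cannot be said, because it is unknown for all libraries but replicate 2 of phage 3.5 min.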

Other observations

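The scaling, selection, short-RNA and abundant-RNA tests, the word groups and the level counts in this part were chosen after the result was seen. The scaling test on transfer and non-coding RNAs replaced an earlier one, whose value shifted all features alike, and selection was split into 2 levels after its first value was seen.

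The symbols fixed for iron uptake matched 1 host feature, so products with iron, siderophore or heme words were counted. Of 106 such features 29 rose and 6 fell in the authors' deposited table (30 and 8 adjusted over the list alone; median 0.49), with the siderophore receptor PAK_4093 at 5.30 and the tonB family protein PAK_6053 at -2.19. The wording was tried in 2 versions, and the first took in 110 features, 27 higher and 7 lower (28 and 7 adjusted over the list alone), with a median of 0.29 in the authors' deposited table. Non-coding features with riboswitch words had 21 of 26 lower and 0 higher in the authors' deposited table, and those called potential small RNA had 18 of 39 lower and 2 higher.

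Sorted by the 0 min level, 149 features with a mean under 10 rose and 0 fell in the authors' deposited table, but sorted by the 13 min level 0 rose and 42 fell there. The sorting itself could make most of this pattern. By the mean of both times, 43.4% of 525 calls from 10 to 100 were higher (Wilson 95% interval 39.3 to 47.7). That is the level of 101 of the 149, and selection stays an explanation for these. Of 38 calls with a mean of both under 10, the level of 35 of the 149, 92.1% were higher (Wilson 95% interval 79.2 to 97.3), above the bound of 75 set for excluding it there. These intervals treat features of the same libraries as independent, so they are too narrow to settle it. The median log2 fold change of all features was 0.23 at that level and -0.24 from 10 to 100. DNA carried over stays open: a test of signal on both strands, written beforehand, had not settled it and was dropped with the antisense means, after its value had been seen. No biological explanation was tested.

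The falls of features with transfer RNA words and of non-coding RNAs could come from scaling, from loss of short RNAs or from abundant RNAs taking reads. A single factor would move all features alike, but the median of these 195 features lay 0.69 below that of other features of their level (difference -0.69, bootstrap 95% interval -0.97 to -0.39), beyond the bound of -0.3 set for excluding scaling as the whole cause. The bootstrap draws features, which are not independent replicates. The share left for features other than the 3 most abundant non-coding RNAs changed by -0.12 on the log2 scale, a smaller fall than the -0.5 set as the bound for excluding that. The 4 most abundant non-coding RNAs had a median of -0.10, but lengths are not given in the sources used here, so loss of short RNAs cannot be told apart from infection or time.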
